A study of Mus musculus with 23 samples.

How the data were processed

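RNA was measured in CD11b+ cells taken from mouse spleen with magnetic beads, per the labels. CD11b is an integrin chain carried by neutrophils, monocytes and many macrophages. The recipients were irradiated female C57BL/6 mice, either wild type (WT) or lacking the low density lipoprotein receptor (Ldlr-/-). They received marrow from mice carrying the Jak2 V617F mutation under an Mx1-Cre driver (Jak2 VF) or from control littermates. Per the labels, the Ldlr-/- recipients ate a Western-type diet for 7 weeks, starting 4 weeks after transplant, and the WT recipients ate chow. Polyadenylated RNA was selected and libraries were made with NEB kits, per the labels' protocols. The submitters' processing notes name cutadapt, HISAT2, Subread, featureCounts and DESeq2 and the genome build mm10. Their versions, settings, strand option and gene annotation are not given in the sources used here.

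The deposited table holds whole-number read counts per transcript row, not normalized by the authors, for all 23 libraries. It has 32850 rows of 24059 symbols. There are 4813 symbols with several rows, and their 13604 rows hold 2.33% of all counts. The median total count over all libraries was 129 for symbols with a single row and 16 for symbols with several rows. Itgam, which encodes CD11b itself, had 0 counts over 2 rows, Gapdh had 129 and Ldlr had 0. Low counts of genes with several overlapping transcripts therefore need not mean low expression, and such genes are named here with their number of rows. Coordinates are those of the deposited table, on mm10. The authors also deposited a table of their own DESeq2 results for each Jak2 VF comparison. Per the file headers, these tables give the authors' mean normalized count as a signal, a log2 fold change with its standard error, a Wald statistic or score, p-values and a fold (ratio) on RPKM. They list only genes with adjusted p up to 0.05 and an RPKM ratio of at least 2 either way, as their values show.

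The counts were tested as deposited with edgeR 4.0.16 in R 4.3.3. Rows were kept by filterByExpr with a minimum count of 10 and a minimum total count of 15, which left 11207 rows, here called genes. Library sizes were scaled by TMM, and all 23 libraries entered 1 quasi-likelihood fit with the 4 groups as the only term. The contrasts were Jak2 VF against control marrow within each recipient setting, the difference between these effects, and the Western-diet Ldlr-/- setting against the chow WT setting within each marrow. P-values were adjusted by Benjamini-Hochberg over all genes of a contrast, and a gene was called at an adjusted p under 0.05. "Rose" and "fell" are used only of called genes. A fold change is given on the log2 scale as estimate ± standard error (SE). Levels are TMM-scaled CPM, as mean ± standard deviation (SD). The labels do not say that libraries of a group came from separate mice, so p-values measure only the spread between these libraries. Recipient genotype and diet changed together, and their effects cannot be separated in this design.

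Total counts per library ran from 7976855 to 10998545. In data simulated from these means and library sizes with 200 changed genes, the same fit on 11057 genes recovered 55.1%, 75%, 98% and 100% of changes of 1.5-, 2-, 4- and 8-fold in the chow comparison, with 8 false calls. For the Western-diet comparison it recovered 40.8%, 64.6%, 92% and 98.0%, with 6 false calls. Only the 200 changed genes differed between the simulated groups, with as many set to rise as to fall. The false calls therefore do not show the error rate in the real comparisons, where 44.5% and 54.7% of genes were called.

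Gene lists were fixed before the data were examined, as were the contrasts, the tests, the rule for named genes and most of the alternative settings. There were 34 lists with 809 symbols, of which 774 matched the count table, 20 of them through a synonym, and 609 had a tested row. The list of mitochondrially encoded genes was not analysed here, and 33 lists were tested. The lists covered erythroid, megakaryocyte and platelet, neutrophil primary granule, neutrophil secondary granule, mature neutrophil, monocyte, red pulp macrophage, dendritic, B, plasma, T, NK, basophil and mast, eosinophil, stem and progenitor, and stromal and endothelial cells. The others covered MHC class II presentation, JAK2-STAT5 targets, interferon response, inflammasome and interleukin-1, Ifi200-family and other DNA sensors, NF-kB and cytokines, mitosis, DNA replication, DNA repair, p53 targets, cholesterol synthesis, LXR targets, glycolysis and hypoxia, oxidative phosphorylation, efferocytosis, iron, heme and NRF2, and immediate early genes. Each list was tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the lists of a contrast. Camera asks whether a list moved more than the other genes. The same test with the correlation estimated from the residuals, and fry, which asks whether a list moved on balance in either direction, were alternatives. A list score is the mean log2 CPM of its tested members in a library. Lists of pancreatic acinar genes and of patrolling monocyte genes were made after the data were seen. On simulated data camera called a planted list and 0 of 30 random lists, again on 11057 genes. The simulated genes were drawn independently of each other, so this does not show how often camera calls lists of correlated genes. In the real libraries the estimated correlation reached 0.871 for the erythroid list.

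Named genes followed a fixed rule. Jak2, Aim2, Il1b, Il18, Casp1, Nlrp3 and Gsdmd are always given. Each Jak2 VF comparison names the 8 largest rises and 8 largest falls among called genes with an average log2 CPM of at least 2 and every Jak2 VF library on the same side of the control mean. The difference of effects and each setting comparison name the 5 largest each way by that rule, without the condition on libraries for the difference. Predicted genes, clone names and variable segments of antigen receptors were skipped. From each list described, up to 4 members with the smallest adjusted p were taken. The alternative settings were the scaling (size factors of DESeq2, or library totals alone), no filter or a stricter filter (1 CPM in 6 samples), DESeq2 1.42.0, limma-voom, a robust fit, a fit of only the groups compared, the replicate number as a term, a 2-fold threshold and each library left out in turn. Alternatives added after the data were seen were counts summed over the rows of a symbol, a fit without control chow library 2, Jak2 VF chow library 6 and Jak2 VF Western library 4, and a fit without the Rn45s and Mir6236 rows. Libraries of a group were compared before averaging: no pair held identical values, and chi-square per degree of freedom between pairs was 4.80 to 76.9, so all 23 were kept as separate samples.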

Results

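The study concerned clonal hematopoiesis driven by the activating Jak2 V617F mutation and the Aim2 inflammasome, a sensor of cytosolic DNA that activates caspase-1. RNA of CD11b+ spleen cells was counted in 23 libraries from mice transplanted with control or Jak2 VF marrow. There were 6 libraries with control marrow and 7 with Jak2 VF marrow from chow-fed WT recipients (control chow and Jak2 VF chow). A further 6 with control marrow and 4 with Jak2 VF marrow came from Western-diet-fed Ldlr-/- recipients (control Western and Jak2 VF Western). Total counts were 7976855 to 9342560 in control chow, 8445277 to 9603320 in Jak2 VF chow, 8709184 to 10712961 in control Western and 9857028 to 10998545 in Jak2 VF Western.

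The marrow genotype and the recipient setting both separated the libraries on the component that held 51.7% of the variance, and the next held 10.4%. Neutrophil granule genes took a large part of the reads in some groups: the 10 most abundant rows held 11.98% to 17.1% of the counts in Jak2 VF Western libraries and 5.56% to 9.47% in the others. Counts of the secondary granule list made up 1.51 ± 0.28% of all counts in control chow (SD, n = 6), 6.02 ± 1.12% in Jak2 VF chow (n = 7), 3.86 ± 1.22% in control Western (n = 6) and 12.6 ± 2.02% in Jak2 VF Western (n = 4). TMM factors accordingly fell to 0.744 to 0.962 in Jak2 VF Western. Scaling by library totals alone, without these factors, shifted the median log2 fold change of all genes by -0.107 in the chow Jak2 VF comparison, -0.290 in the Western-diet one, -0.181 in their difference, -0.0716 between settings with control marrow and -0.251 with Jak2 VF marrow. Changes below are relative to the TMM scale.

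**Figure D1:**
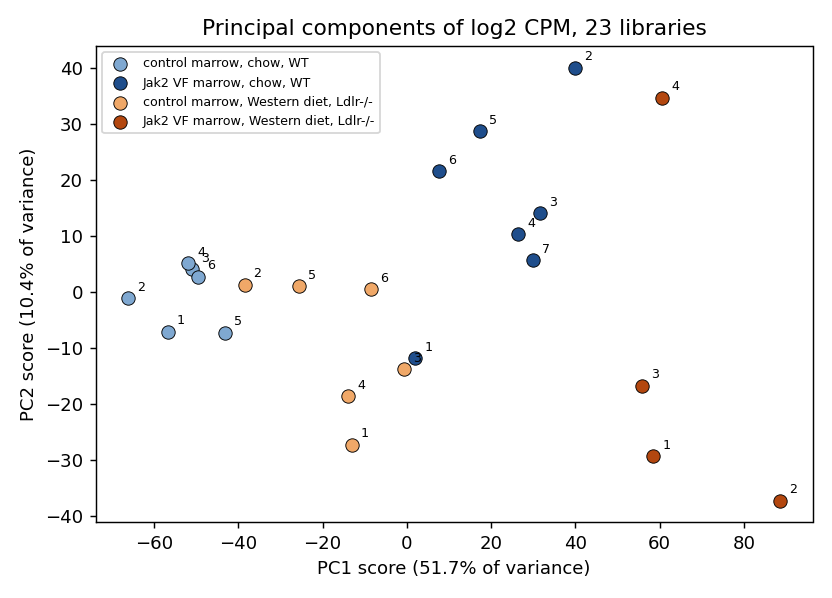
Scores of the 23 libraries on the principal components of log2 CPM that hold 51.7% (horizontal axis) and 10.4% (vertical axis) of the variance, with points coloured by marrow and recipient setting and numbered by replicate. Control chow libraries sit at the left and Jak2 VF Western libraries at the right.

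Jak2 itself had few counts in the deposited table (178 over all libraries, in 2 rows) and did not enter the tests. The tabulated level was 0.914 ± 0.494 CPM in control chow (SD, n = 6) and 0.761 ± 0.197 CPM in Jak2 VF chow (n = 7; exact two-sided permutation test, p = 0.467). It was 0.872 ± 0.145 CPM in control Western (n = 6) and 0.775 ± 0.401 CPM in Jak2 VF Western (n = 4; exact two-sided permutation test, p = 0.614). With 3 to 14 counts per library no difference was detectable at this depth, and a point mutation need not change the count, so the level does not check the labels. Aim2 (chromosome 1, 173420604 to 173466036, plus strand) was at 109 ± 4.13 CPM in control chow, 94.6 ± 15.1 in Jak2 VF chow, 107 ± 9.27 in control Western and 66.3 ± 7.03 in Jak2 VF Western.

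The chow-fed WT recipients showed what Jak2 VF marrow changed in the bead-isolated spleen cells without the lipid challenge. In either setting the values do not separate a changed makeup of the isolated cells from changed expression within CD11b+ cells. Genes of the red cell lineage rose most. Gypa (chromosome 8, 80494045 to 80510785, plus strand), which encodes glycophorin A of the red cell membrane, went from 7.02 ± 4.94 CPM (SD, n = 6) to 244 ± 222 CPM (n = 7), a log2 fold change of 5.12 ± 0.80 (adjusted p = 2.47e-05). Rhag, the Rh-associated glycoprotein, rose by 5.47 ± 0.84 (adjusted p = 1.99e-05) and Slc4a1, the band 3 anion exchanger, by 5.35 ± 0.89 (adjusted p = 5.05e-05). The other largest rises were Slfn14 (5.23 ± 0.73), Apol8 (5.22 ± 0.93), Apol11b (5.19 ± 0.81), the erythroid non-coding RNA Redrum (5.13 ± 0.86) and Trim58 (5.11 ± 0.81). Every Jak2 VF library lay above the control mean for each of these 8 genes, which the rule for naming them required. In the erythroid list 23 of 24 members rose (23 adjusted over the list alone), with a median of 4.12 (camera adjusted p = 5.63e-12, adjusted p = 0.368 with an estimated correlation). The spread was wide: erythroid scores ran from 3.64 in Jak2 VF chow library 1 to 7.74 in library 2, against 1.46 to 2.98 in control chow.

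Genes of neutrophil granules and of cell division also rose with Jak2 VF marrow in chow-fed recipients. All 23 tested members of the secondary granule list rose (23 adjusted over the list alone), with a median of 2.84 (camera adjusted p = 1.21e-15, adjusted p = 0.368 with an estimated correlation). Among them the chitinase-like Chil3 went from 637 to 4579 CPM (2.84 ± 0.29, adjusted p = 3.26e-07), Cd177 rose by 2.96 ± 0.35 and Anxa1 by 2.21 ± 0.27. The primary granule list had 10 rises and 2 falls among 14 members (10 and 2 adjusted over the list alone; median 2.04, camera adjusted p = 6.60e-04, adjusted p = 0.368 with an estimated correlation). Its examples were Cebpe, a transcription factor of granulocyte maturation (3.02 ± 0.37), Fcnb (3.50 ± 0.44) and Ms4a3 (3.25 ± 0.45). Of 22 mature neutrophil genes 20 rose and 1 fell (20 and 1 adjusted over the list alone; median 1.18, camera adjusted p = 4.89e-09, adjusted p = 0.368 with an estimated correlation). Among them were the alarmin S100a8 (2.40 ± 0.31) and the formyl peptide receptor Fpr2 (1.97 ± 0.24). All 24 mitosis genes rose (24 adjusted over the list alone; median 2.07, camera adjusted p = 1.31e-18, adjusted p = 0.368 with an estimated correlation). Among them were Anln (2.31 ± 0.23) and the mitotic kinase Cdk1 (1.97 ± 0.22). All 27 DNA replication genes rose as well (27 adjusted over the list alone; median 1.12, camera adjusted p = 3.28e-11, adjusted p = 0.368 with an estimated correlation). E2f8 stood at 2.63 ± 0.23 and the ribonucleotide reductase subunit Rrm2 at 2.29 ± 0.28. DNA repair genes, several of which follow the cell cycle, showed 18 rises and 3 falls among 24 (18 and 3 adjusted over the list alone; median 1.39, camera adjusted p = 4.97e-07, adjusted p = 0.396 with an estimated correlation). Fanca stood at 1.40 ± 0.15 and Eme1 at 2.14 ± 0.24.

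Genes of B cells, T cells and resident macrophages fell. Ms4a1 (chromosome 19, 11250603 to 11266151, minus strand), which encodes the B cell antigen CD20, went from 404 ± 109 CPM (SD, n = 6) to 65.9 ± 19.4 CPM (n = 7), a log2 fold change of -2.62 ± 0.26 (adjusted p = 2.94e-07). Among the other largest falls were complement receptor Cr2 (-2.57 ± 0.29), the kinase Blk (-2.55 ± 0.25) and the adhesion molecule Cd2 (-2.59 ± 0.29), all carried by lymphocytes. The ubiquitin-like Ubd (-3.65 ± 0.32, adjusted p = 8.70e-08), the prostacyclin synthase Ptgis (-3.41 ± 0.41), Gdpd3 (-3.15 ± 0.49) and the sphingosine 1-phosphate receptor S1pr3 (-2.97 ± 0.22) completed the 8. All 8 lay below the control mean in 7 of 7 Jak2 VF libraries, which the rule for naming them required. Gdpd3 was at 6.90 CPM in control chow library 1, below every Jak2 VF chow library (8.99 to 52.6 CPM). In the other control chow libraries it was at 186 to 262 CPM. In the B cell list 14 of 15 members fell (14 adjusted over the list alone; median -2.23, camera adjusted p = 1.76e-10, adjusted p = 0.368 with an estimated correlation). In the T cell list 14 of 15 fell (14 adjusted over the list alone; median -1.50, camera adjusted p = 3.47e-04, adjusted p = 0.546 with an estimated correlation). Cd28 stood at -1.55 ± 0.35 and Cd5 at -1.37 ± 0.29. Plasma cell genes fell in 9 of 11 cases (9 adjusted over the list alone; median -0.98, camera adjusted p = 1.62e-04, adjusted p = 0.368 with an estimated correlation), led by Mzb1 (-2.50 ± 0.29). Of 23 red pulp macrophage genes 14 fell (16 adjusted over the list alone; median -0.86, camera adjusted p = 2.03e-04, adjusted p = 0.703 with an estimated correlation). Among them were the efferocytosis receptor Mertk (-1.80 ± 0.27), the integrin Itgad (-1.60 ± 0.31) and Vcam1 (-1.37 ± 0.29). MHC class II presentation genes fell in 12 of 13 cases (12 adjusted over the list alone; median -0.57, camera adjusted p = 8.27e-05, adjusted p = 0.368 with an estimated correlation). H2-Ob stood at -1.45 ± 0.18.

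Inflammasome genes did not move as a group in chow-fed recipients. Of 22 members of the inflammasome and interleukin-1 list 3 rose and 6 fell (2 and 6 adjusted over the list alone), with a median of 0.06, a mean of -0.02 and camera adjusted p = 0.755. Il18 fell by 0.82 ± 0.24 (adjusted p = 0.00786, lower in 7 of 7 Jak2 VF libraries), and the guanylate-binding protein Gbp5 changed by -0.89 ± 0.13. Casp1 fell by 0.27 ± 0.09 (adjusted p = 0.0232, lower in 6 of 7) and the pore-forming Gsdmd rose by 0.24 ± 0.10 (adjusted p = 0.0476, higher in 7 of 7). Aim2 was lower in 5 of 7 Jak2 VF libraries and was not called (-0.20 ± 0.09, adjusted p = 0.0592). It was called on library totals alone (-0.31, adjusted p = 0.0109), by limma-voom (-0.22, adjusted p = 0.0417) and without Jak2 VF chow library 1 (-0.23, adjusted p = 0.0199) or 5 (-0.25, adjusted p = 0.0221). Il1b (0.03 ± 0.23, adjusted p = 0.930) and Nlrp3 (-0.10 ± 0.12, adjusted p = 0.532) were not called. The Casp1 call was lost with no filter on low counts (adjusted p = 0.0669) and without control chow library 2 or Jak2 VF chow library 2, 3, 4 or 7 (adjusted p = 0.0519 to 0.0796). The Gsdmd call was lost on library totals (adjusted p = 0.186) and without control chow library 2, 3, 4 or 6 or Jak2 VF chow library 1, 2, 4 or 5 (adjusted p = 0.0532 to 0.105).

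Over all 11207 tested genes, 4982 were called in the chow comparison, 2427 higher and 2555 lower, and 1582 of them changed at least 2-fold. On library totals the split was 1887 higher and 3519 lower. Genes of pancreatic acinar cells, a list made after the data were seen, were called higher in 8 of 18 cases by edgeR (18 adjusted over the list alone), and in 0 of 18 without Jak2 VF chow library 6, where all 18 stood highest (1 at an unadjusted p under 0.05).

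**Figure D2:**
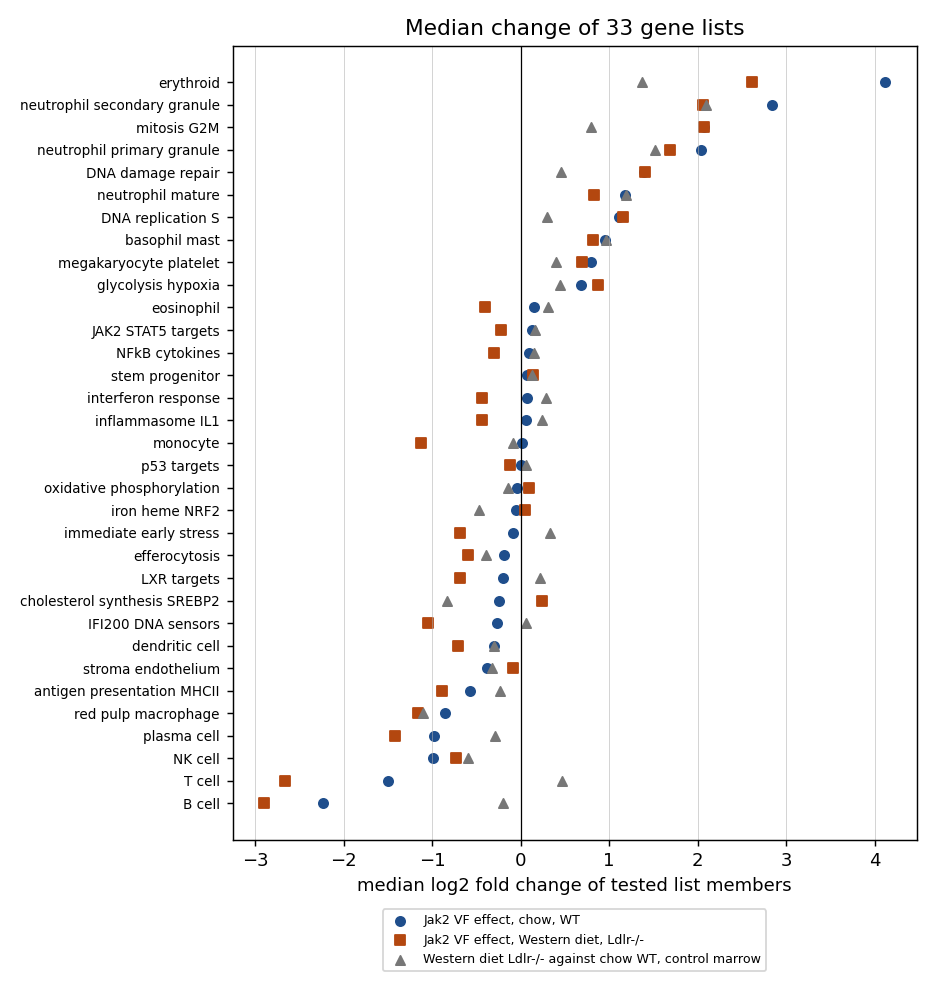
Median log2 fold change (horizontal axis) of the tested members of each of 33 gene lists (vertical axis) for the Jak2 VF effect in chow-fed WT recipients (circles), in Western-diet-fed Ldlr-/- recipients (squares) and for the setting difference with control marrow (triangles). Erythroid and secondary granule genes had Jak2 VF medians from 2.06 to 4.12, and B cell genes -2.23 and -2.90.

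In Western-diet-fed Ldlr-/- recipients, Aim2 fell with Jak2 VF marrow. Its level was 66.3 ± 7.03 CPM (SD, n = 4) against 107 ± 9.27 CPM (n = 6), a log2 fold change of -0.69 ± 0.10 (adjusted p = 1.01e-05), lower in 4 of 4 Jak2 VF libraries. The Ifi200-family and other DNA sensors, to which Aim2 belongs, fell in 10 of 11 cases and rose in 1 (10 and 1 adjusted over the list alone; median -1.05, camera adjusted p = 0.00128, adjusted p = 0.476 with an estimated correlation). Mndal (-1.58 ± 0.20) and Pyhin1 (-1.37 ± 0.18) belong to the same gene cluster, whose members are near-identical in part, so their counts are uncertain where the counting could split shared reads. Of 22 inflammasome and interleukin-1 genes 11 fell and 2 rose (12 and 2 adjusted over the list alone; median -0.44), and the list was not called (camera adjusted p = 0.0656, adjusted p = 0.518 with an estimated correlation). The list was called by fry (adjusted p = 0.00190), with no filter on low counts (adjusted p = 0.0177), with the replicate number as a term (adjusted p = 0.0275) and without control Western library 2 or 6 or Jak2 VF Western library 1 or 2 (camera adjusted p = 0.0311 to 0.0392). Il18 fell by 0.96 ± 0.29 (adjusted p = 0.00798), Nlrp3 by 0.48 ± 0.14 (adjusted p = 0.00736), Casp1 by 0.31 ± 0.11 (adjusted p = 0.0239), Gbp5 by 1.40 ± 0.16 and Nlrc4 by 0.83 ± 0.15. The Casp1 call was lost with the size factors of DESeq2 (-0.26, adjusted p = 0.0534) and without Jak2 VF Western library 4 (-0.19, adjusted p = 0.130). Il1b, the gene of interleukin-1 beta, was not called (-0.47 ± 0.27, adjusted p = 0.143), except on library totals (-0.77, adjusted p = 0.0148) and without control Western library 2 (-0.64, adjusted p = 0.0220). Gsdmd was not called either (0.04 ± 0.11, adjusted p = 0.809), and on library totals it turned to -0.28 (adjusted p = 0.0146).

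Neutrophil and cell division genes rose again. All 23 secondary granule genes rose (23 adjusted over the list alone; median 2.06, camera adjusted p = 5.05e-09, adjusted p = 0.476 with an estimated correlation). Among them were Chil3 (2.36 ± 0.31), Ifitm6 (2.01 ± 0.24) and Anxa1 (2.06 ± 0.29). Primary granule genes rose in 10 of 14 cases and fell in 2 (10 and 2 adjusted over the list alone; median 1.68, camera adjusted p = 0.00862, adjusted p = 0.476 with an estimated correlation). Fcnb stood at 2.93 ± 0.45 and Cebpe at 2.37 ± 0.39. Mature neutrophil genes rose in 16 of 22 cases (18 adjusted over the list alone; median 0.83, camera adjusted p = 8.65e-05, adjusted p = 0.476 with an estimated correlation). S100a8 stood at 1.83 ± 0.33. All 24 mitosis genes (24 adjusted over the list alone; median 2.07, camera adjusted p = 4.28e-13, adjusted p = 0.476 with an estimated correlation) and all 27 DNA replication genes (27 adjusted over the list alone; median 1.16, camera adjusted p = 1.18e-08, adjusted p = 0.476 with an estimated correlation) rose, among them the kinase Aurkb (1.73 ± 0.20) and E2f8 (2.24 ± 0.24). The LIM-only transcription cofactor Lmo1 (3.27 ± 0.30, adjusted p = 1.04e-07) and the pseudokinase Trib3 (3.22 ± 0.57) were among the 8 largest rises. Trib3 was at 38.8 CPM in Jak2 VF Western library 4 and 5.59 to 14.2 CPM in the others of that group, against 1.10 to 2.43 CPM in control Western.

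Most of the other largest rises were red cell genes, and these leaned on a single library. Snca (4.12 ± 0.93, 2 rows), Apol11b (3.66 ± 0.80), the erythroblast hormone Fam132b (3.38 ± 0.71), Trim10 (3.34 ± 0.75), Redrum (3.26 ± 0.76) and Slfn14 (3.21 ± 0.73) were higher in 4 of 4 Jak2 VF Western libraries, again as the rule required. In the erythroid list 22 of 24 members rose (23 adjusted over the list alone; median 2.61, camera adjusted p = 8.57e-04, adjusted p = 0.518 with an estimated correlation). DESeq2 called 22 of these 24 and limma-voom 10. The erythroid score was 7.54 in Jak2 VF Western library 4 and 4.01 to 4.81 in the other 3 libraries of that group, against 1.81 to 4.21 in control Western. Without library 4 the list had 3 rises of 24, a median of 0.76 and camera adjusted p = 0.0525. Gypa (3.09 ± 0.76) then stood at 1.64 (adjusted p = 0.0523), Fam132b at 1.29 (adjusted p = 0.0565) and Redrum at 1.52 (adjusted p = 0.0683), all no longer called. Trim10 stayed called at 2.18 and Tfrc, the transferrin receptor (2.64 ± 0.50), at 1.41.

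Lymphocyte, monocyte, macrophage and dendritic cell genes fell. The B cell gene Ms4a1 went from 342 ± 106 CPM (SD, n = 6) to 38.4 ± 17.2 CPM (n = 4), a log2 fold change of -3.15 ± 0.34 (adjusted p = 3.09e-07), and Blk fell by 3.20 ± 0.32. All 15 B cell genes (15 adjusted over the list alone; median -2.90, camera adjusted p = 5.05e-09, adjusted p = 0.476 with an estimated correlation) and all 15 T cell genes (15 adjusted over the list alone; median -2.66, camera adjusted p = 7.12e-06, adjusted p = 0.476 with an estimated correlation) fell. Plasma cell genes fell in 8 of 11 cases (9 adjusted over the list alone; median -1.42, camera adjusted p = 0.00165, adjusted p = 0.476 with an estimated correlation). Of 16 monocyte genes 13 fell and 1 rose (13 and 1 adjusted over the list alone; median -1.13, camera adjusted p = 0.00125, adjusted p = 0.476 with an estimated correlation). The transcription factors Irf8 (-1.52 ± 0.20) and Nr4a1 (-1.60 ± 0.22) were among the falls, and Ly6c2, a marker of classical monocytes, was the rise (1.59 ± 0.22). Red pulp macrophage genes fell in 19 of 23 cases (19 adjusted over the list alone; median -1.16, camera adjusted p = 4.47e-04, adjusted p = 0.518 with an estimated correlation). The complement receptor Vsig4 stood at -2.14 ± 0.50 and Siglec1 at -1.36 ± 0.28. Dendritic cell genes fell in 13 of 17 cases (14 adjusted over the list alone; median -0.71, camera adjusted p = 0.00168, adjusted p = 0.476 with an estimated correlation). The chemokine receptor Ccr7 stood at -1.19 ± 0.17. MHC class II genes fell in 12 of 13 (12 adjusted over the list alone; median -0.89, camera adjusted p = 5.08e-06, adjusted p = 0.476 with an estimated correlation). The remaining largest falls were Atp6v0d2, a subunit of the vacuolar proton pump (-3.99 ± 0.46, adjusted p = 6.40e-07), Hs3st1 (-3.75 ± 0.40), Gdpd3 (-3.56 ± 0.63), Tmem163 (-3.21 ± 0.36), Sspn (-3.15 ± 0.47) and Scn4a (-3.14 ± 0.47).

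Interferon-stimulated and LXR target genes fell as well. Of 31 interferon genes 16 fell and 2 rose (16 and 2 adjusted over the list alone; median -0.43, camera adjusted p = 0.0115, adjusted p = 0.518 with an estimated correlation). The tetherin gene Bst2 stood at -0.98 ± 0.15 and Ifit3 at -0.84 ± 0.14. Of 19 LXR targets 14 fell and 2 rose (14 and 2 adjusted over the list alone; median -0.69, camera adjusted p = 0.00814, adjusted p = 0.476 with an estimated correlation). Aim2 is also a member of this list as it was fixed, lay at its median and is counted among its 14 falls. Whether LXR controls Aim2 was not tested, and its place in the list is no evidence of that. The falls included the fatty acid enzymes Scd1 (-2.31 ± 0.28) and Fasn (-0.82 ± 0.15), which SREBP-1 also controls. Over all genes 6135 were called, 2946 higher and 3189 lower, and 2203 changed at least 2-fold. On library totals the split was 1532 higher and 5233 lower.

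**Figure D3:**
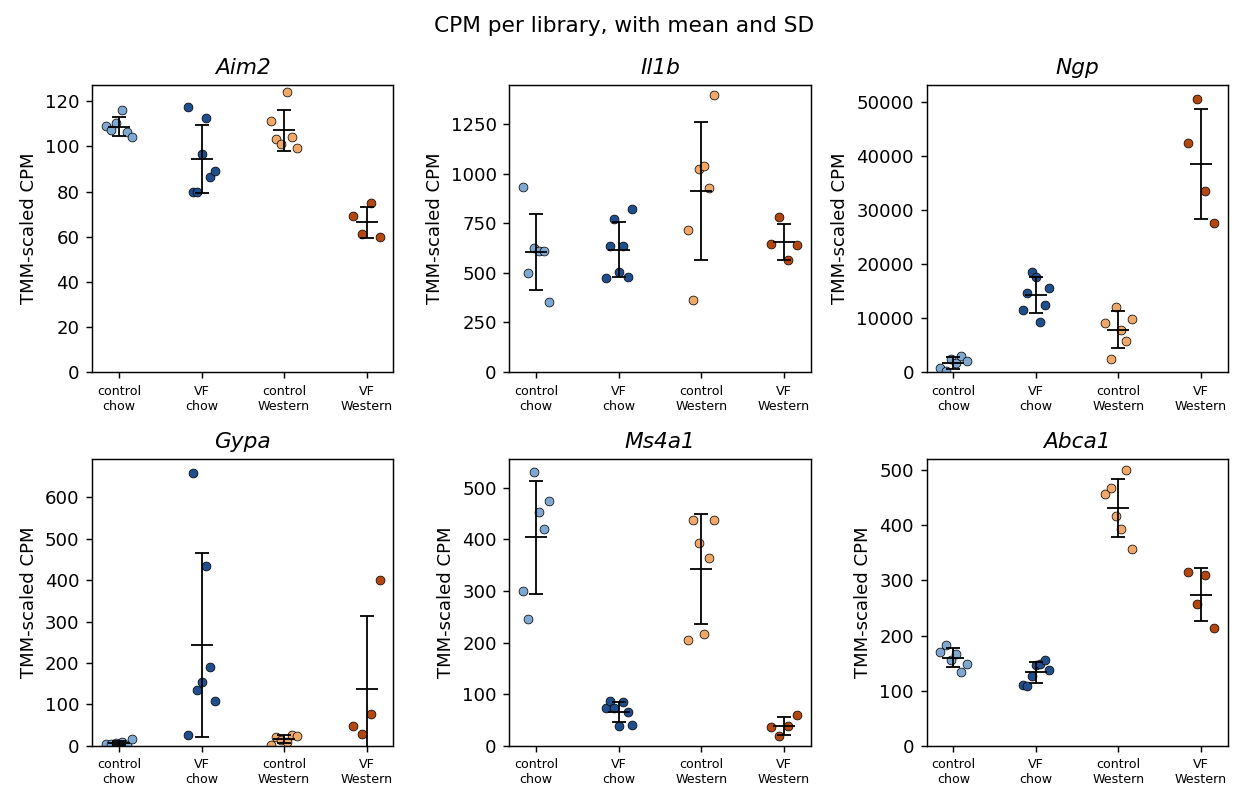
TMM-scaled CPM (vertical axes, from 0) of Aim2, Il1b, Ngp, Gypa, Ms4a1 and Abca1 in each library of the 4 groups, where a point is a library, the wide line the group mean and the bar the SD, drawn down to 0 at most. Aim2 lay between 59.8 and 74.9 CPM in the 4 Jak2 VF Western libraries and between 79.7 and 124 CPM in the other 19.

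The Jak2 VF effects in the 2 settings, which share no libraries, went the same way for most genes called in both. There were 1984 genes higher and 2011 lower in both settings, against 638 and 727 for independent lists of the same sizes, and 19 called in opposite directions against 1362. Across genes, which are not independent replicates, the log2 fold changes had Pearson's r = 0.835 and Spearman's rho = 0.828. The slope of the Western-diet on the chow effect was 0.884. The authors' deposited tables list 1968 genes for the chow and 2692 for the Western-diet comparison. Of these, 1615 and 2462 were tested here, all with the sign in the authors' deposited table, and 1596 and 2426 were called. Aim2 is in neither of the authors' deposited tables, which hold only changes of at least 2-fold.

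**Figure D4:**
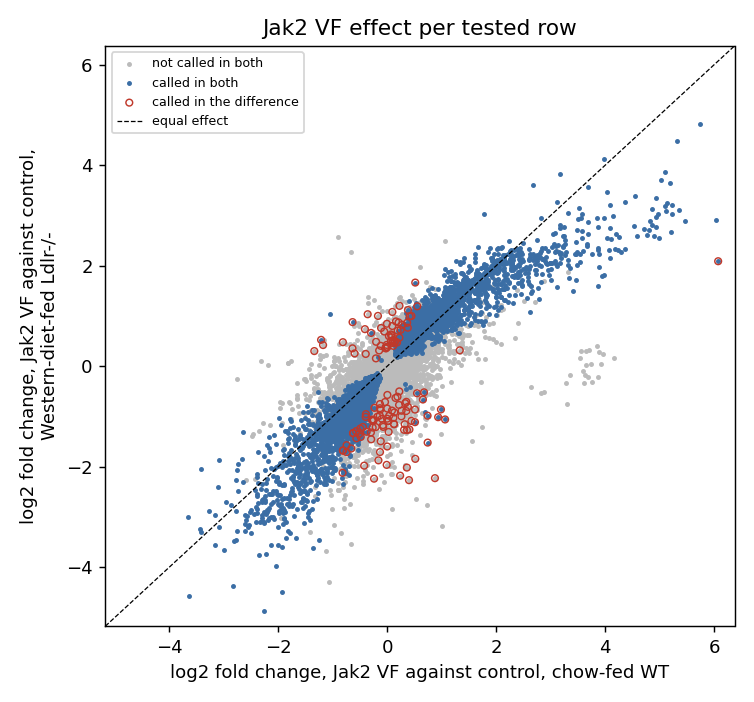
Log2 fold change of Jak2 VF against control marrow for each of 11207 genes in chow-fed WT recipients (horizontal axis) and Western-diet-fed Ldlr-/- recipients (vertical axis), with genes called in both settings and genes called in the difference marked and equal effects dashed. Most genes called in both lie on the same side of 0 on both axes (1984 higher, 2011 lower, 19 opposite).

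The difference between the 2 effects asked which genes responded to Jak2 VF marrow differently in Western-diet-fed Ldlr-/- recipients. Every gene called in it by edgeR lost that call with the replicate number as a term (0 genes called), a pairing the labels do not state. Monocyte genes had the more negative effect there. Of 16 members 3 were called lower in the difference (9 adjusted over the list alone; median -0.73, camera adjusted p = 5.06e-07, adjusted p = 0.439 with an estimated correlation). Nr4a1 and Klf4, transcription factors in this list, differed by -1.60 ± 0.28 (adjusted p = 0.0135) and -1.63 ± 0.35 (adjusted p = 0.0309). Cecr6 (-3.10 ± 0.61, adjusted p = 0.0226) and the sphingosine 1-phosphate receptor S1pr5 (-2.67 ± 0.55, adjusted p = 0.0292) had the largest negative differences. Sned1 (1.74 ± 0.27, adjusted p = 0.0135) and Myo18b (1.64 ± 0.32, adjusted p = 0.0231) had the largest positive ones, and Ptgs1, which encodes cyclooxygenase-1, differed by 1.39 ± 0.26 (adjusted p = 0.0190). The interferon list was lower in 5 of 31 cases (15 adjusted over the list alone; median -0.60, camera adjusted p = 1.78e-09, adjusted p = 0.439 with an estimated correlation). Ifit3 stood at -0.84 ± 0.18 (adjusted p = 0.0309). The DNA sensor list was lower in 1 of 11 (10 adjusted over the list alone; median -0.78, camera adjusted p = 7.11e-06, adjusted p = 0.439 with an estimated correlation). Aim2 differed by -0.49 ± 0.13 and was not called (adjusted p = 0.0657), so its effect is not shown to differ between settings. The Aim2 difference was called by DESeq2 (-0.47, adjusted p = 0.0240), on library totals (-0.67, adjusted p = 0.0159), with counts summed over rows (-0.52, adjusted p = 0.0495) and without Jak2 VF chow library 2 or 3 or Jak2 VF Western library 3 (adjusted p = 0.0289 to 0.0462). Il1b (-0.50 ± 0.35, adjusted p = 0.485), Il18 (-0.14 ± 0.37, adjusted p = 0.884), Casp1 (-0.03 ± 0.15, adjusted p = 0.934), Nlrp3 (-0.38 ± 0.19, adjusted p = 0.312) and Gsdmd (-0.20 ± 0.15, adjusted p = 0.500) were not called. With 1 library left out, the members called lower ran from 1 to 6 of 16 for monocytes, 0 to 8 of 31 for interferon and 0 to 3 of 11 for DNA sensors. Monocytes had 1 without control chow library 2 or 3, Jak2 VF chow library 5 or Jak2 VF Western library 2. Interferon genes had 0 by edgeR without control chow library 1, 2 or 3, Jak2 VF chow library 5 or Jak2 VF Western library 2, where 15 to 17 had an unadjusted p under 0.05. Without Jak2 VF Western library 2, Cecr6, S1pr5, Ptgs1, Klf4 and Ifit3 were not called (adjusted p = 0.0706 to 0.0941). Without control chow library 3 or Jak2 VF chow library 5, S1pr5, Klf4 and Ifit3 were not called, nor were Klf4 and Ifit3 without control chow library 2 or Ifit3 without control chow library 1 (adjusted p = 0.0507 to 0.0561).

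T cell, B cell, dendritic, MHC class II and erythroid genes also had lower medians in the difference, and cholesterol synthesis genes a higher median. These lists were called by camera with medians of -1.16 for T cells (adjusted p = 2.52e-04, adjusted p = 0.481 with an estimated correlation) and -0.66 for B cells (adjusted p = 0.00881, adjusted p = 0.704 with an estimated correlation). The medians were -0.49 for dendritic cells (adjusted p = 0.00488, adjusted p = 0.481 with an estimated correlation) and -0.41 for MHC class II (adjusted p = 4.79e-04, adjusted p = 0.481 with an estimated correlation). No member of these 4 lists was called over all genes by edgeR; adjusted over the list alone there were 4 T cell and 4 dendritic cell genes. At an unadjusted p under 0.05 there were 5 T cell, 2 B cell, 5 dendritic and 3 MHC class II genes. DESeq2 called 2 T cell and 2 dendritic genes and limma-voom 0 in the 4 lists. The B cell list was not called without control Western library 6 or Jak2 VF Western library 2 (adjusted p = 0.0580 and 0.137). Erythroid genes had a median of -1.59 with 0 of 24 called by edgeR, 0 by DESeq2 and 1 at an unadjusted p under 0.05 (camera adjusted p = 7.11e-06, adjusted p = 0.519 with an estimated correlation). Without Jak2 VF Western library 4 their median was -3.37 and 17 of 24 were called lower (22 at an unadjusted p under 0.05). Cholesterol synthesis genes were higher in 2 of 21 cases (7 adjusted over the list alone; median 0.33, camera adjusted p = 9.91e-04, adjusted p = 0.439 with an estimated correlation). That median was 0.0630 without Jak2 VF Western library 4, where 3 genes were called, and 0.105 without the 3 libraries that stood apart. None was called by edgeR without control chow library 1 or 3, Jak2 VF chow library 5, control Western library 4 or Jak2 VF Western library 1, where 8 to 10 had an unadjusted p under 0.05. The B cell median was -1.01 without Jak2 VF Western library 4 and -0.402 without library 2, and the MHC class II median -0.271 without library 2. LXR targets were lower in 2 of 19 (4 adjusted over the list alone; median -0.39, camera adjusted p = 0.00774, adjusted p = 0.481 with an estimated correlation) and inflammasome genes in 0 of 22 by edgeR, 1 by DESeq2 and 5 at an unadjusted p under 0.05 (1 adjusted over the list alone; median -0.33, camera adjusted p = 0.00774, adjusted p = 0.481 with an estimated correlation). Without Jak2 VF Western library 4 neither was called (adjusted p = 0.113 and 0.370). Without the 3 libraries that stood apart the dendritic, cholesterol, LXR and inflammasome lists were not called (adjusted p = 0.0505 to 0.168), and on library totals the B cell list was not (adjusted p = 0.192). By fry the monocyte, interferon and DNA sensor lists were called (adjusted p = 0.0313 to 0.0372), and the 8 lists of this paragraph were not (adjusted p = 0.0813 to 0.318). The JAK2-STAT5 list was also called lower by fry (adjusted p = 0.0128). In all, 137 genes were called in the difference, 51 higher and 86 lower, and 59 differed at least 2-fold. On library totals the split was 25 higher and 446 lower. The count was 40, 43, 32, 65 and 73 without control chow library 1, 2, 3, 4 or 6, 23 without Jak2 VF chow 5, 60, 43 and 86 without control Western 2, 4 or 5, and 80, 14, 248 and 562 without Jak2 VF Western 1, 2, 3 or 4.

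With control marrow, the Western-diet-fed Ldlr-/- recipients had lower cholesterol synthesis genes and higher Abca1 and Abcg1. Insig1, a sterol sensor, went from 57.7 ± 13.7 CPM in control chow (SD, n = 6) to 20.1 ± 3.62 CPM in control Western (n = 6), a log2 fold change of -1.52 ± 0.15 (adjusted p = 1.19e-06). Idi1 (-2.22 ± 0.25), Cyp51 (-1.81 ± 0.21), Stard4 (-1.57 ± 0.15) and Dhcr24 (-2.81 ± 0.38, adjusted p = 1.05e-04) fell too. In the cholesterol synthesis list 16 of 21 members fell and 1 rose (18 and 1 adjusted over the list alone; median -0.84, camera adjusted p = 5.45e-17, adjusted p = 0.00635 with an estimated correlation), the only list of this comparison called with an estimated correlation. Abca1 (chromosome 4, 53030789 to 53159895, minus strand), the cholesterol exporter, went from 159.8 ± 17.7 to 432 ± 52.5 CPM (n = 6 each; 1.44 ± 0.11, adjusted p = 4.57e-08), and Abcg1 rose by 0.87 ± 0.11. LXR targets rose in 6 of 19 cases and fell in 1 (7 and 2 adjusted over the list alone; median 0.21, camera adjusted p = 0.0163, adjusted p = 0.439 with an estimated correlation); without control Western library 5 the list was not called (adjusted p = 0.0503).

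Neutrophil genes were also higher in the Western-diet setting with control marrow. Of 23 secondary granule genes 21 rose (23 adjusted over the list alone; median 2.10, camera adjusted p = 3.16e-17, adjusted p = 0.335 with an estimated correlation), with Mmp8, the neutrophil collagenase (2.61 ± 0.39, adjusted p = 1.86e-04), and Olfm4 (2.82 ± 0.49) among them. Mature neutrophil genes rose in 20 of 22 cases and fell in 1 (20 and 1 adjusted over the list alone; median 1.18, camera adjusted p = 2.73e-14, adjusted p = 0.348 with an estimated correlation). Retnlg stood at 2.47 ± 0.34. Mitosis genes rose in 18 of 24 (23 adjusted over the list alone; median 0.79, camera adjusted p = 8.37e-10, adjusted p = 0.439 with an estimated correlation). Interferon genes rose in 11 of 31 (14 adjusted over the list alone; median 0.29, camera adjusted p = 3.78e-05, adjusted p = 0.439 with an estimated correlation). Oas3 stood at 1.23 ± 0.20. Red pulp macrophage genes fell in 16 of 23 cases and rose in 1 (18 and 1 adjusted over the list alone; median -1.10, camera adjusted p = 3.50e-07, adjusted p = 0.439 with an estimated correlation). The falls included Spic, a transcription factor of these macrophages (-1.46 ± 0.25), and Trf (-1.40 ± 0.27), and the rise was Vsig4 (2.38 ± 0.43). The largest rises were the eosinophil granule genes Epx (3.34 ± 0.66, adjusted p = 0.00114) and Ear1 (3.05 ± 0.60). Pnpla1 stood at 2.79 ± 0.46. The largest falls were Hs3st2 (-4.21 ± 0.39, adjusted p = 8.13e-07), Retnla (-4.04 ± 1.03), Cbr2 (-3.36 ± 0.25) and Col14a1 (-2.93 ± 0.47). Retnla was not called by limma-voom (-2.27, adjusted p = 0.183) or without control chow library 6 (-1.72, adjusted p = 0.114).

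Aim2 did not differ detectably between settings with control marrow (-0.02 ± 0.09, adjusted p = 0.878), nor did Il1b (0.59 ± 0.24, adjusted p = 0.0830) or Casp1 (-0.12 ± 0.10, adjusted p = 0.405). Il18 fell by 0.78 ± 0.25 (adjusted p = 0.0292), while Nlrp3 (0.36 ± 0.13, adjusted p = 0.0477) and Gsdmd (0.33 ± 0.10, adjusted p = 0.0214) rose. The Nlrp3 call was lost by limma-voom, on library totals, with no filter on low counts and in the fit of the 2 groups alone (adjusted p = 0.0519 to 0.0869). It was also lost without control chow library 2, 3, 4, 5 or 6 or control Western library 3, 4, 5 or 6 (adjusted p = 0.0545 to 0.102). The Il18 call was lost without control chow library 1 or 2 or control Western library 3, 4 or 6 (adjusted p = 0.0608 to 0.0945), and the Gsdmd call without control chow library 2 (adjusted p = 0.0589). Il1b was called without control chow library 1 (adjusted p = 0.0340) or control Western library 2 (adjusted p = 0.00921). In all 2221 genes were called, 1310 higher and 911 lower, and 559 at least 2-fold. On library totals the split was 1088 higher and 1157 lower.

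With Jak2 VF marrow, the same setting difference again lowered cholesterol synthesis genes and raised Abca1. Insig1 changed by -1.55 ± 0.17, Cyp51 by -2.06 ± 0.24 and Dhcr24 by -2.37 ± 0.44, and in the list 11 of 21 fell and 2 rose (12 and 2 adjusted over the list alone; median -0.54, camera adjusted p = 1.76e-04, adjusted p = 0.475 with an estimated correlation). Abca1 rose by 1.04 ± 0.12 (adjusted p = 2.01e-05) and Abcg1 by 0.64 ± 0.12. The LXR list split into 5 rises and 7 falls (5 and 7 adjusted over the list alone; median -0.29, camera adjusted p = 0.822). Aim2 fell by 0.51 ± 0.10 (adjusted p = 5.38e-04), lower in 4 of 4 Jak2 VF Western libraries than the Jak2 VF chow mean, and by 0.77 on library totals. DNA sensor genes fell in 8 of 11 cases (10 adjusted over the list alone; median -0.73, camera adjusted p = 0.00235, adjusted p = 0.475 with an estimated correlation). Secondary granule genes rose in 21 of 23 (23 adjusted over the list alone; median 1.34, camera adjusted p = 3.00e-07, adjusted p = 0.475 with an estimated correlation). Monocyte genes fell in 12 of 16 and rose in 1 (13 and 1 adjusted over the list alone; median -0.97, camera adjusted p = 1.59e-05, adjusted p = 0.475 with an estimated correlation). Klf4 stood at -1.63 ± 0.27 and Nr4a1 at -1.41 ± 0.21. Red pulp macrophage genes fell in 17 of 23 (18 adjusted over the list alone; median -1.10, camera adjusted p = 1.05e-05, adjusted p = 0.566 with an estimated correlation). Among them were Siglec1 (-1.70 ± 0.28) and the complement gene C1qa (-1.40 ± 0.31). Dendritic cell genes fell in 13 of 17 (14 adjusted over the list alone; median -0.79, camera adjusted p = 5.71e-05, adjusted p = 0.475 with an estimated correlation) and MHC class II genes in 12 of 13 (12 adjusted over the list alone; median -0.68, camera adjusted p = 1.05e-05, adjusted p = 0.475 with an estimated correlation).

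The largest rises in this comparison were the acyl-CoA thioesterase Acot1 (2.30 ± 0.30, adjusted p = 4.03e-05), Ggt1 (2.21 ± 0.38), Pnpla1 (1.90 ± 0.37), Lct (1.64 ± 0.30) and Chil1 (1.63 ± 0.28). The largest falls besides Dhcr24 were Col14a1 (-3.36 ± 0.57), Hs3st2 (-3.00 ± 0.45), Cecr6 (-2.83 ± 0.49) and Gp2 (-2.45 ± 0.89), a pancreatic zymogen granule gene. Without Jak2 VF chow library 6, which stood apart in acinar genes, Gp2 stood at -0.52 and was not called (adjusted p = 0.333), nor was it by DESeq2 (-0.53, adjusted p = 0.266), by limma-voom, in the fit of the 2 groups alone or without Jak2 VF Western library 1, 2 or 4 (adjusted p = 0.0588 to 0.193). Il18 fell by 0.92 ± 0.28 (adjusted p = 0.0131), a call lost without Jak2 VF Western library 2 (adjusted p = 0.0782), and Il1b (0.09 ± 0.26), Casp1 (-0.16 ± 0.11), Nlrp3 (-0.02 ± 0.14) and Gsdmd (0.13 ± 0.11) were not called (adjusted p = 0.802, 0.254, 0.920 and 0.351). Casp1 was called on library totals (-0.43, adjusted p = 0.00186) and Gsdmd without Jak2 VF Western library 4 (adjusted p = 0.0468). In all 4469 genes were called, 2278 higher and 2191 lower, and 814 at least 2-fold. On library totals the split was 878 higher and 4281 lower, and without Jak2 VF Western library 2 the count was 2837. Of the genes called between settings, 992 were higher and 585 lower with either marrow, against 266 and 178 for independent lists, and 11 went in opposite directions, against 441. Across genes the fold changes of the 2 setting comparisons, which share no libraries, had Pearson's r = 0.600.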

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

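The tests of dilution, scaling, loss of B and T cells, neutrophil RNA, Aim2 per cell and pancreas tissue, and the counts over other splits of the libraries and over redrawn residuals, were chosen after the results were seen. The contrast of the 2 Jak2 VF effects was not.

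By the contrast of the effects in edgeR, the Jak2 VF effect differed between the 2 recipient settings for 137 genes. None of them, Sned1 and Myo18b included, stayed called with the replicate number as a term (0 genes called), a pairing the labels do not state. The largest positive differences were those of Sned1 (1.74), Myo18b (1.64), Galnt3 (1.60), Cbr2 (1.51) and Ptgs1 (1.39). The largest negative ones were those of Cecr6 (-3.10), S1pr5 (-2.67), Cyp2ab1 (-2.42), Vegfc (-2.38) and Ace, the angiotensin-converting enzyme (-2.36, 3 rows). The Sned1 and Myo18b calls held with any library left out. The Ace, Vegfc and Cyp2ab1 calls were lost without control chow library 1, 2, 3 or 4, Jak2 VF chow library 5, control Western library 2 or 4 or Jak2 VF Western library 2, and those of Ace and Vegfc also without control chow library 6 (adjusted p = 0.0506 to 0.101). Ace was also lost without Jak2 VF Western library 1. The Galnt3 call was lost without control chow library 1, 2 or 3, Jak2 VF chow library 5, control Western library 4 or Jak2 VF Western library 1 or 2 (adjusted p = 0.0507 to 0.0865). The Cbr2 call was lost without control chow library 1 to 4, Jak2 VF chow library 1, 3, 4 or 5, control Western library 1 to 5 or Jak2 VF Western library 1 or 2 (adjusted p = 0.0512 to 0.0972). The Cecr6 and Ptgs1 calls were lost without Jak2 VF Western library 2 (adjusted p = 0.0833 and 0.0706), and S1pr5 also without control chow library 3 or Jak2 VF chow library 5 (adjusted p = 0.0526 to 0.0865). The count itself was 14 without Jak2 VF Western library 2 and 562 without library 4.

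The difference was called for 14 of 33 gene lists by camera, and for 0 with an estimated correlation (3 at an unadjusted p under 0.05). The monocyte list had a median difference of -0.73, DNA sensors -0.78, interferon genes -0.60, T cells -1.16, B cells -0.66, erythroid genes -1.59, dendritic cells -0.49, MHC class II -0.41, LXR targets -0.39, inflammasome genes -0.33 and cholesterol synthesis 0.33. Without Jak2 VF Western library 4 the erythroid median was -3.37, with 17 of 24 genes called lower, the B cell median -1.01 and the cholesterol synthesis median 0.0630. Without library 2 the B cell median was -0.402 and the MHC class II median -0.271, and the LXR median was -0.259 without Jak2 VF chow library 6 and -0.253 without control Western library 5. Without Jak2 VF Western library 2 edgeR called 0 of 31 interferon genes, against 5 with it (17 at an unadjusted p under 0.05), and 1 of 16 monocyte genes, against 3. Immediate early genes had a median of -0.53, with 2 of 21 called lower (3 adjusted over the list alone; camera adjusted p = 9.91e-04, adjusted p = 0.481 with an estimated correlation), and fry did not call them (adjusted p = 0.0843). JAK2-STAT5 targets had a median of -0.52, with 2 of 18 called lower (3 adjusted over the list alone; camera adjusted p = 0.00733, adjusted p = 0.409 with an estimated correlation), led by the survival gene Bcl2 (-1.56 ± 0.29, 2 rows). Fry called the JAK2-STAT5 list lower (adjusted p = 0.0128). With 1 library left out, the members called lower ran from 0 to 3 for JAK2-STAT5 targets, 1 to 2 for immediate early genes and 0 to 4 for LXR targets. Without Jak2 VF Western library 2 Bcl2 was not called (adjusted p = 0.0706), and without library 4 the JAK2-STAT5 list was not (adjusted p = 0.0503). Oxidative phosphorylation genes had a median of 0.0936 with 0 of 27 called by edgeR, 5 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma-voom (1 adjusted over the list alone; camera adjusted p = 0.00124, adjusted p = 0.519 with an estimated correlation). On library totals their median turned to -0.08, not called (adjusted p = 0.290), and without Jak2 VF Western library 4 their median was 0.00509 and the list was not called either (adjusted p = 0.270). Without the 3 libraries that stood apart the median was 0.0286, again not called (adjusted p = 0.232), and with Jak2 VF chow library 1, 3 or 7 or control Western library 1, 3 or 4 left out it was 0.0505 to 0.0601. The inflammasome (adjusted p = 0.370) and LXR lists (adjusted p = 0.113) were also lost without Jak2 VF Western library 4, as was the B cell list without control Western library 6 or Jak2 VF Western library 2 (adjusted p = 0.0580 and 0.137).

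By camera the B cell, T cell and red pulp macrophage lists fell and the neutrophil granule and erythroid lists rose with Jak2 VF marrow, calls that were lost with an estimated correlation (adjusted p = 0.368 to 0.703), and the erythroid call in the Western-diet setting was also lost without Jak2 VF Western library 4 (median 0.763 against 2.61, adjusted p = 0.0525). Dilution of all other cells by 1 factor would lower their lists alike, and the change of the B cell score minus that of the monocyte score was -1.95 in chow-fed recipients (SD 0.540), which argues against it. Another scaling adds 1 amount to all genes of a library and so cannot part 2 lists. In 17 of 18 pairs of a rising and a falling list the changes differed by more than 2 SD. The exception was erythroid and red pulp macrophage genes in the Western-diet setting (2.85, SD 1.83). This parting argues against scaling as the whole source. The lists were picked for having risen or fallen in these libraries, so the count of pairs is not an independent test. B and T cells, which mostly lack CD11b, could have been lost by 1 factor at the bead isolation: the change of the B cell score minus that of the T cell score was -0.757 in chow (SD 0.366), just over 2 SD and so weakly against this, while at -0.367 in the Western-diet setting (SD 0.404) it cannot be told apart from fewer such cells in the spleen. A changed makeup of the spleen with Jak2 VF marrow was not tested and stays open.

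Aim2 fell with Jak2 VF marrow in Western-diet-fed recipients. Its log2 fold change nearest 0 under another scaling was -0.645 (SE 0.101), which argues against a scaling error of the size of those shifts (0.0448 and -0.290 over all genes). A line of Aim2 CPM on the share of secondary granule counts in the 19 other libraries (slope -3.38 CPM per percent, residual SD 10.2 CPM) put the Jak2 VF Western mean at 73.6 CPM, and the measured 66.3 CPM lay -7.26 CPM from it. Dilution by RNA of neutrophils may account for part of the fall and cannot be told apart from a change in Aim2 itself, because within groups Aim2 correlated with that share at -0.379 in control chow and -0.612 in Jak2 VF chow but 0.00806 in control Western, and because the shares of 10.1% to 14.5% in these libraries lie beyond the highest of 7.499% behind the line. Lower Aim2 in the cells that express it cannot be told apart from fewer such cells, since Aim2 lay 0.468 (SE 0.102) above the lowest of the monocyte, dendritic and red pulp macrophage medians.

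Acinar genes were called higher in Jak2 VF chow libraries, and all 18 stood highest in library 6, with Ctrb1 at 600.3 CPM and Pnlip at 460.1 CPM against at most 45.4 and 27.7 CPM elsewhere. Pancreas tissue taken with the spleen is a candidate source, although the CD11b isolation would remove acinar cells: without library 6, 0 of 18 genes were called by edgeR (1 at an unadjusted p under 0.05), against 8 with it, while DESeq2 called 0 of 18 with all libraries and gave 4 no adjusted p. An effect of Jak2 VF marrow on all chow libraries was argued against, as 0 of the 6 other Jak2 VF chow libraries had an acinar score above the highest control chow library.

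The numbers of genes called in 4 of the comparisons were each set against 100 splits of the same libraries. The real split gave the most genes in each (a share of 0.01), which argues against chance as far as the libraries are independent. In the chow Jak2 VF comparison 1 split, the real one, gave as many as 4982 genes, and the highest other gave 3294. In the Western-diet comparison 1 split gave as many as 6135, and the highest other 3658. Between settings 1 split gave as many as 2221 with control marrow and 1 as many as 4469 with Jak2 VF marrow, and the highest others gave 1100 and 3327. For the difference of the effects the splits exchanged settings within each marrow and so carried the setting effect into the difference: 4 of 100, the real one included, gave at least 137 genes, the highest other gave 2950, and they do not measure chance. With the additive effects of marrow and setting kept and the residuals of the libraries redrawn, limma called 124 genes in the real arrangement and at most 1 in 99 others, so that 1 of 100 gave as many. For the difference this argues against chance only as far as the libraries vary alike and independently of each other. It leaves open a variation shared by libraries of the same replicate number.

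A single library lay far from the rest of its group in 9 of 172 groups of values, where chance alone gives 8.6. The monocyte score was 8.33 in control chow library 1 (7.83 to 7.99 in the others) and 8.50 in Jak2 VF chow library 1 (7.72 to 7.94). Casp1 was at 136 CPM in Jak2 VF chow library 1 (86.6 to 106 in the others). The primary granule score was 7.63 in Jak2 VF Western library 2 (7.12 to 7.18), and the eosinophil score there was 3.92 (4.75 to 4.82). The NF-kB score was 4.19 in control Western library 2 (4.75 to 5.04) and the basophil score 1.56 in control chow library 2 (2.05 to 2.24). The acinar score was 7.21 in Jak2 VF chow library 6 (-1.85 to 0.41). The ribosomal Rn45s row took 1.64% of the counts in control chow library 2 (0.266% to 0.669%).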

How the results depend on the processing

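The sums over the rows of a symbol, the fit without the 3 libraries that stood apart and the fit without the Rn45s and Mir6236 rows were chosen after the data were seen. Comparisons are given in the order chow Jak2 VF effect, Western-diet Jak2 VF effect, difference of the effects, setting with control marrow and setting with Jak2 VF marrow. Of the results for named genes, 705 kept their direction and side of the threshold with the size factors of DESeq2, 679 with DESeq2 (33 gained a call, 3 lost it), 693 with limma-voom, 692 with no filter, 663 without the 3 libraries, 660 with the replicate block as a term (3 gained a call, 52 lost it) and 655 on library totals. On library totals 31 gained and 27 lost a call and 2 reversed: Gsdmd for the Western-diet Jak2 VF effect at -0.276 (adjusted p = 0.0146) and Ndufb3 for the setting with Jak2 VF marrow at -0.0866 (adjusted p = 0.379). Leaving out 1 library kept 9277 gene results, while 97 gained and 448 lost a call. The causes were not tested.

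With a 2-fold change also required, 1582, 2203, 59, 559 and 814 genes were left. The difference of the effects gave 471 genes on library totals, 465 with DESeq2, and 349 without the 3 libraries (195 higher and 154 lower). With counts summed over rows it split into 37 higher and 121 lower. With 1 library left out, the counts ran from 4512 to 5106, 5144 to 6306, 14 to 562, 1514 to 2462 and 2837 to 5281. The correlation of the Jak2 VF effects between settings was 0.491 with no filter on low counts, and 0.763 to 0.845 with 1 library left out. Aim2 in the chow comparison was called at -0.308 on library totals and -0.217 by limma-voom, and ran from -0.249 to -0.136 with 1 library left out. In the Western-diet comparison it ran from -0.754 to -0.639. The Jak2 level, limited by its 3 to 14 counts per library, differed by -0.265 CPM on library totals in the Western-diet comparison, by -0.294 to -0.000409 CPM with 1 library left out, and by -0.264 to -0.0185 CPM in chow.

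Camera called 16, 21, 14, 19 and 16 of 33 lists with the preset correlation and 0, 0, 0, 1 and 0 with the correlation estimated, where 4, 1, 3, 3 and 1 had an unadjusted p under 0.05. Fry, which does not compare a list with other genes, called 19, 26, 4, 16 and 18. Without the 3 libraries camera called 8 lists in the difference. With 1 library left out it called 14 to 16, 18 to 23, 11 to 17, 17 to 22 and 15 to 18.

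With the replicate block as a term edgeR called 4344, 5689, 0, 1827 and 3733 genes, and 1611 genes of the difference had an unadjusted p under 0.05. All 137 calls of the difference, and so those of all genes named for it, were lost under the block. The labels do not say that the replicate numbers pair the libraries, and the values do not show it for all numbers: the residuals of same-numbered libraries had correlations of -0.324 to 0.383 (median 0.0673), over 0.1 in 14 of 30 pairs, and a library correlated best with its own number in 20 of 60 cases, where chance gives 10.6. The 6 pairs of libraries numbered 1 all correlated, at 0.177 to 0.383, so a shared source of variation among some numbers is not excluded.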

Other observations

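The patrolling monocyte list, and the members of it that are counted, were chosen after the results were seen, and the other lists were not. Glycolysis and hypoxia genes rose with Jak2 VF marrow in both settings. In chow-fed recipients 15 of 20 rose and 1 fell (15 and 1 adjusted over the list alone; median 0.69, camera adjusted p = 8.25e-06, adjusted p = 0.368 with an estimated correlation). In Western-diet-fed recipients 16 rose and 2 fell (16 and 2 adjusted over the list alone; median 0.87, camera adjusted p = 6.85e-05, adjusted p = 0.476 with an estimated correlation). The endoplasmic reticulum oxidase Ero1l rose by 1.69 ± 0.17 and 1.83 ± 0.18, and the glycolytic enzymes Pgk1 by 0.76 ± 0.11 and 1.19 ± 0.12 and Pgam1 by 0.90 ± 0.12 and 1.33 ± 0.13. The list also rose between settings with control marrow, in 8 of 20 cases (10 adjusted over the list alone; median 0.44, camera adjusted p = 3.47e-05, adjusted p = 0.371 with an estimated correlation). The basophil and mast cell list rose in 7 of 12 cases in chow (7 adjusted over the list alone; median 0.96, camera adjusted p = 0.0157, adjusted p = 0.396 with an estimated correlation). Among the rises were Il18rap (1.72 ± 0.21), the lipoxygenase Alox5 (1.67 ± 0.24) and the histidine decarboxylase Hdc (1.32 ± 0.22), which neutrophils also express. In the Western-diet comparison 6 of 12 rose (6 adjusted over the list alone; median 0.82, camera adjusted p = 0.0243, adjusted p = 0.476 with an estimated correlation), a call lost without Jak2 VF Western library 4 (adjusted p = 0.0575). In the stem and progenitor list 4 of 14 rose and 3 fell in chow (4 and 3 adjusted over the list alone; median 0.08, camera adjusted p = 0.452). The transcription factor Erg stood at 2.29 ± 0.32 and Hlf at 2.10 ± 0.27. Targets of NRF2 were among the rises of the iron, heme and NRF2 list (Nqo1 1.99 ± 0.29, Gclm 1.26 ± 0.25), in which 5 of 15 rose and 5 fell (6 and 5 adjusted over the list alone; median -0.05, camera adjusted p = 0.620).

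Of the patrolling monocyte genes tested, 7 had not been picked for their difference in these libraries. They were still listed after the results were seen, so their counts are not an independent test. With Jak2 VF marrow 5 of these 7 fell in the Western-diet setting (5 adjusted over the list alone; median -1.31), and 2 rose in chow (1 adjusted over the list alone; median 0.04). In the difference 2 were lower (6 adjusted over the list alone; median -1.12). With Jak2 VF chow library 5 or Jak2 VF Western library 2 left out edgeR called 0 of them, with 6 and 5 at an unadjusted p under 0.05, and it called 1 with any of 15 other libraries left out. NK cell genes fell in 3 of 14 cases in chow (3 adjusted over the list alone; median -0.99, camera adjusted p = 0.0492, adjusted p = 0.739 with an estimated correlation). That call was lost on library totals (adjusted p = 0.118) and without control chow library 1, 5 or 6 or Jak2 VF chow library 3, 6 or 7 (adjusted p = 0.0577 to 0.102). The replicate number as a term (adjusted p = 0.0774) and a fit without the 3 libraries that stood apart (adjusted p = 0.0558) ended it too. In the Western-diet setting 6 fell (6 adjusted over the list alone; median -0.73, camera adjusted p = 0.0342, adjusted p = 0.518 with an estimated correlation). This Western-diet call too was lost on library totals (adjusted p = 0.237) and without control Western library 3 or Jak2 VF Western library 2 or 4 (adjusted p = 0.0504 to 0.114). It was also lost without the 3 libraries that stood apart (adjusted p = 0.0662). Immediate early genes fell with Jak2 VF marrow in the Western-diet setting in 9 of 21 cases (8 adjusted over the list alone; median -0.69, camera adjusted p = 0.0324, adjusted p = 0.518 with an estimated correlation). Among them were the phosphatase Dusp2 (-1.68 ± 0.17) and Egr2 (-1.54 ± 0.28). That call was lost on library totals (adjusted p = 0.101) and without control Western library 3 or Jak2 VF Western library 3 (adjusted p = 0.0510 to 0.0559). Efferocytosis genes fell between settings in 7 of 17 cases with control marrow, where 1 rose (7 and 1 adjusted over the list alone; median -0.39, camera adjusted p = 0.00622, adjusted p = 0.439 with an estimated correlation). With Jak2 VF marrow 11 fell (13 adjusted over the list alone; median -0.98, camera adjusted p = 0.00125, adjusted p = 0.475 with an estimated correlation). The complement gene C1qb stood at -1.15 ± 0.25 with control marrow and -1.30 ± 0.29 with Jak2 VF marrow. Oxidative phosphorylation genes fell between settings with control marrow in 5 of 27 cases (11 adjusted over the list alone, median -0.14, camera adjusted p = 6.34e-05, adjusted p = 0.439 with an estimated correlation). With Jak2 VF marrow edgeR called 2 of 27, and camera did not call the list except on library totals (median -0.277, adjusted p = 0.0199).

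Megakaryocyte and platelet genes rose in 7 of 16 cases and fell in 1 in the chow Jak2 VF comparison (8 and 2 adjusted over the list alone; median 0.79, camera adjusted p = 0.0492, adjusted p = 0.708 with an estimated correlation). The platelet glycoprotein Gp9 stood at 1.94 ± 0.41 and the chemokine Pf4 at 1.31 ± 0.38. The list was not called with the size factors of DESeq2 (adjusted p = 0.0662), with a stricter filter (adjusted p = 0.0711) or without control chow library 1 to 4 or Jak2 VF chow library 2, 3, 4, 5 or 7 (adjusted p = 0.0546 to 0.0958). Its camera call was also lost with the replicate number as a term (adjusted p = 0.0793), without the 3 libraries that stood apart (adjusted p = 0.0743) and without the Rn45s and Mir6236 rows (adjusted p = 0.0704). Interferon genes in chow were split into 10 rises and 4 falls of 31 (10 and 5 adjusted over the list alone; median 0.07, camera adjusted p = 0.226), from Rsad2 at 2.35 ± 0.38 to Ifi44 at -1.15 ± 0.20. JAK2-STAT5 targets rose in 8 of 18 cases and fell in 3 (8 and 5 adjusted over the list alone; median 0.13, camera adjusted p = 0.616). The feedback inhibitor Cish stood at 1.51 ± 0.24 and Id1 at 1.26 ± 0.22. In the Western-diet comparison 4 of the 18 targets rose and 7 fell (4 and 7 adjusted over the list alone), with a median of -0.218. Camera did not call the list there (adjusted p = 0.405), and fry called it lower (adjusted p = 0.00116). In the chow comparison, eosinophil genes (3 rises and 3 falls of 10, 3 and 3 adjusted over the list alone; camera adjusted p = 0.958) included the interleukin-5 receptor Il5ra at -2.00 ± 0.25. NF-kB and cytokine genes in chow (3 and 3 of 20, 2 and 3 adjusted over the list alone; camera adjusted p = 0.620) were not called as a list. Neither, in chow, were p53 targets (5 and 4 of 22, 5 and 4 adjusted over the list alone; camera adjusted p = 0.826) or stromal and endothelial genes (1 and 4 of 11, 1 and 4 adjusted over the list alone; camera adjusted p = 0.615). Erythroid genes had a median of 1.37 between settings with control marrow (camera adjusted p = 0.00603, adjusted p = 0.582 with an estimated correlation), with 0 of 24 called by edgeR or limma-voom, 4 by DESeq2 and 8 at an unadjusted p under 0.05.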
